A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

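CPD-seq reads from 1 library, labelled as wild-type yeast of strain BY4741 taken before irradiation, were analysed. A raised read density at HIS3 and missing reads at TRP1 went against that strain label. The 4 irradiated samples of the rad16 deletion (125 J/m2, 0 and 2 h of repair) were not analysed here. Per the labels' protocols, DNA was ligated to a first adaptor, free 3-prime ends were blocked, lesions were cut with T4 endonuclease V and APE1, and the new ends were ligated to a second adaptor and amplified by PCR. The submitters' processing notes name Bowtie2 2.2.6, SAMtools, bedtools and the sacCer3 build, without roles or order. Filters on quality, duplicates or dinucleotides are not given in the sources used here.

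The deposited file has 1 line per read, with an interval of 2 bases, a strand and a mapping quality score from 0 to 42, a score that the authors left as it was in the file, with no normalization. All 7925017 intervals are 2 bases long. No selection of dipyrimidines was found in the file, since dipyrimidines made up 25.6% of nuclear reads outside the ribosomal DNA and 26.8% of the same part of the genome. Within 12 bp of the left chromosome ends all 70 lines carry the minus strand and within 12 bp of the right ends all 86 carry the plus strand. The strand was therefore read as that of the presumed lesion, opposite to the sequenced read, with the 2 bases next to the read. The median mapping quality was 42, which 61.5% of reads reached, and 12.9% had a quality of 0 or 1. Such reads can map to more than 1 place, and the values of repeated genes are uncertain for this reason. The reference used was the R64 assembly, whose chromosome lengths are those of sacCer3, with its gene annotation. Coordinates are 1-based. In all, 26 reads lay at or past a chromosome end and had no dinucleotide.

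Reads were counted per position and strand. The expected count of a region was the nuclear mean rate of each dinucleotide, outside the ribosomal DNA (chromosome XII, 451786 to 489469), times the number of such dinucleotides on each strand. The transcribed strand of a gene is the strand opposite to its annotated one. Genes needed an expected count of at least 50, and 5996 of 6002 nuclear protein-coding genes passed. Gene spans run from start to stop codon with introns. Shares have exact binomial and counts exact Poisson 95% intervals, and genes with 0 reads have a limit of 3 reads. Gene lists were compared with 10000 random lists matched on expected count in 10 bins. The tRNA and snoRNA genes were compared with random windows of the same lengths, a departure from the plan that keeps all of their members. The filter passed 68 of 275 tRNA genes and 74 of 76 snoRNA genes. These members were also compared with protein-coding genes matched on expected count, although their mean expected counts of 59.7 and 110.1 lay below the 158.8 of the lowest bin. Origins in the ribosomal DNA were left out, which kept 349 of 352. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

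The fixed lists were deleted markers, nucleotide excision repair, ribosomal proteins, glycolysis and fermentation, glucose-repressed genes, histones, meiosis and sporulation, heat shock, DNA damage response, subtelomeric families, tRNA genes, snoRNA genes and transposon genes. The lists, the tests and the rule for named genes were set before the data were examined. Named genes were the deleted markers with RAD16 and RAD7, the 8 highest and 8 lowest ratios among genes not shared with a near-identical copy by name, the 4 highest and 4 lowest transcribed-strand shares relative to expectation among genes with at least 200 reads, the 2 highest and 2 lowest of each list, and the features at the 5 most hit positions. Copies were recognised from numbered symbols, the COS, PAU and FLO families and overlap with Ty elements. Neighbours of the markers and genes named outside this rule were chosen after their values were seen.

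The counting was tested on simulated reads drawn from the observed dinucleotide rates, with 200 genes changed by known folds. For the gene ratios, all 50 genes at a fold of 0.5, all 50 at 2 and all 50 at 3 passed the threshold of 1.5, as did 12 of 50 at a fold of 1.5, which equals the threshold, and 0 of 5797 unchanged genes. The simulated strand difference was -0.00419 percentage points over 5997 genes, and 0 of 13 lists lay outside the random range. The simulated reads were independent and followed the dinucleotide rates, so unchanged genes lay near their expected counts by construction. The simulation checks the counting and gives no rate of false calls for the real reads. Alternatives counted each position once, left out the most hit positions, chromosome XII, overlapping genes or genes near chromosome ends, moved the position by 1 base, and changed the mapping quality, the expected count, the filters, windows and thresholds. An expected count from 8 bases of context (-4 to 3 relative to the position), the median mapping quality for genes and regions, and the removal of genes with 10% or more of reads at quality 0 or 1 were added after seeing the data, as was the matched comparison of tRNA and snoRNA genes.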

Results

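The series followed the removal of cyclobutane pyrimidine dimers, the main DNA lesion left by ultraviolet light, in budding yeast lacking RAD16. RAD16 and RAD7 encode partners in global genome nucleotide excision repair. Lesions were mapped by CPD-seq, in which T4 endonuclease V and an apurinic endonuclease cut at dimers and the new DNA ends are ligated to an adaptor and sequenced. The labels describe 5 samples. They comprise 1 sample labelled wild type taken before irradiation and 4 samples of the rad16 deletion irradiated with 125 J/m2. Of the 4 irradiated samples, 2 were taken at 0 h and 2 at 2 h of repair. The irradiated samples were not analysed here, so the comparison of repair times was not made. The values below describe the background that the assay gave in the unirradiated library labelled BY4741, a laboratory strain with deleted auxotrophic marker genes. A raised density at HIS3 and missing reads at TRP1 went against that label, as given below. The strain is therefore named here only as labelled. That library held 7925017 reads, of which 7810988 lay on nuclear chromosomes and 114029 on mitochondrial DNA. With 1 library there was no replicate, so no p-value was computed. Unless stated otherwise, intervals are exact 95% intervals, binomial for shares and Poisson for counts. They cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

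The first question was whether reads in unirradiated cells fell at dipyrimidines, the sites where dimers form. Dipyrimidines made up 25.6% of nuclear reads outside the ribosomal DNA (95% interval 25.5 to 25.6%, 1851063 of 7235977 reads). The share of dipyrimidines in the same part of the genome was 26.8%. The complementary dipurines made up 26.0% of reads. Among the dipyrimidines, CT was at 1.05 times its genome share, TT at 0.959, CC at 0.915 and TC at 0.889. The most enriched of the 16 dinucleotides was CG, at 1.34 times its genome share (1.33 to 1.34), followed by AT at 1.10 and CA at 1.06. The lowest was GG at 0.865. The share was not highest at the named position. Moved by 1, 2, 3 and 4 bases in the 5-prime direction it was 23.1%, 22.2%, 24.6% and 25.6%. Moved by 1, 2, 3 and 4 bases in the 3-prime direction it was 25.5%, 25.9%, 26.5% and 26.2%.

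**Figure D1:**
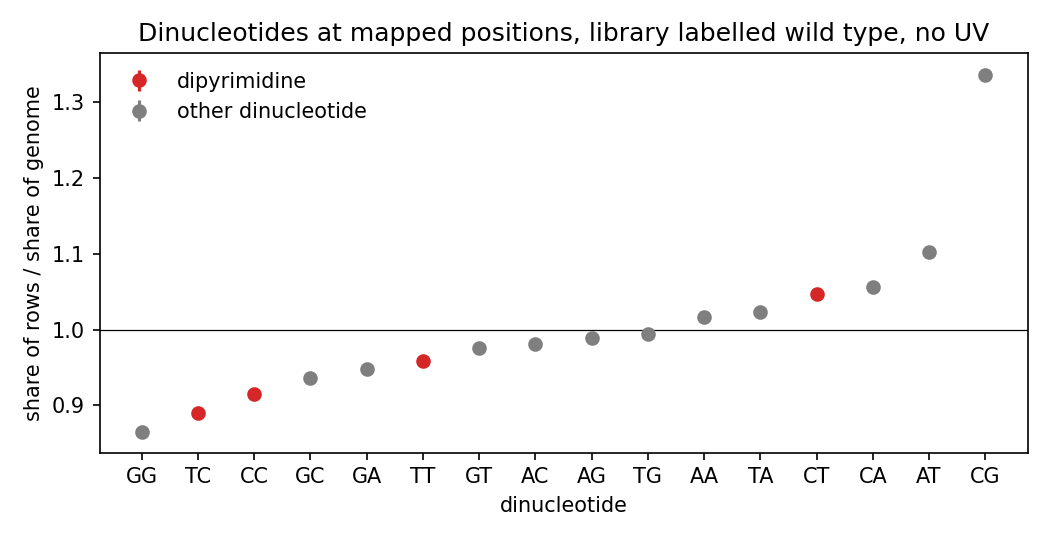
Share of reads at each of the 16 dinucleotides divided by its share of the nuclear genome outside the ribosomal DNA, for the library labelled wild type, without UV. Points are ratios and bars, mostly smaller than the points, are exact Poisson 95% intervals; CG stands at 1.34 and the dipyrimidines lie between 0.889 and 1.05.

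Reads were spread evenly over the nuclear chromosomes, while the ribosomal DNA and mitochondrial DNA stood above them. Density outside the ribosomal DNA was 601.3 reads per kb. Across the 16 chromosomes it ran from 589.9 reads per kb on chromosome II to 621.8 on chromosome VIII. Mitochondrial DNA had 1329 reads per kb, 2.21 times the nuclear mean (2.198 to 2.223). The ribosomal DNA span of chromosome XII (451786 to 489469), which holds the ribosomal RNA genes that are repeated in tandem in the cell, had 25.4 times the nuclear mean (25.3 to 25.4). With each position and strand counted once this ratio was 2.81, and with reads at the median mapping quality only it was 1.92. Both settings lower the ratio of a dense, repeated span by construction. The former ignores further reads at a position already hit. The latter drops reads shared between copies, and density was not adjusted for sequence to which reads cannot map uniquely. Neither value can therefore tell how much of the ratio of 25.4 came from PCR duplicates or mapping. The plus strand of the reference held 49.98% of nuclear reads (49.94 to 50.01%), and 49.8% to 50.3% on single chromosomes.

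The marker genes deleted in whole or part in BY4741 served as a check of the strain. LEU2, a leucine synthesis gene (YCL018W, chromosome III, 91324 to 92418), URA3, a uracil synthesis gene (YEL021W, chromosome V, 116167 to 116970), and MET17, also called MET15, a methionine synthesis gene (YLR303W, chromosome XII, 732542 to 733876), had 0 reads each. From the nuclear mean rate of each dinucleotide, 654.3, 481.7 and 798.9 reads were expected. With a limit of 3 reads, density was at least 218.1-fold lower than expected at LEU2, at least 160.6-fold lower at URA3 and at least 266.3-fold lower at MET17. HIS3, a histidine synthesis gene (YOR202W, chromosome XV, 721946 to 722608), had 806 reads against 396.9 expected, a ratio of 2.03 (1.89 to 2.18). Of the reads in HIS3, 3.72% had a mapping quality of 0 or 1. A deletion of part of a gene leaves reads in the rest of it. The presence of reads at HIS3 was therefore not in itself against the label, while a ratio well above 1 was.

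Most neighbouring genes were near the expected level. NFS1, right of LEU2, had a ratio of 1.13, and the Ty gene YCL019W, left of it, 0.563 (0.537 to 0.590) with 99.9% of reads at mapping quality 0 or 1. GEA2, left of URA3, had a ratio of 1.00 and TIM9, right of it, 1.15. HRI1 and ACO1, on the left and right of MET17, had 1.04 and 1.06, and MRM1 and DED1, beside HIS3, had 1.08 and 1.00. YLR302C, which overlaps MET17, had 35 reads against 218.4 expected, a ratio of 0.160 (0.112 to 0.223). RAD16 (YBR114W, chromosome II, 467248 to 469620) had 1452 reads, a ratio of 1.02 (0.966 to 1.07), and RAD7 (YJR052W, chromosome X, 532062 to 533759) had 1066 reads, a ratio of 1.04 (0.982 to 1.11). TRP1, a tryptophan synthesis gene that is not among the deleted markers of this strain (YDR007W, chromosome IV, 461842 to 462516), had 28 reads against 404.6 expected, a ratio of 0.0692 (0.0460 to 0.10).

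**Figure D2:**
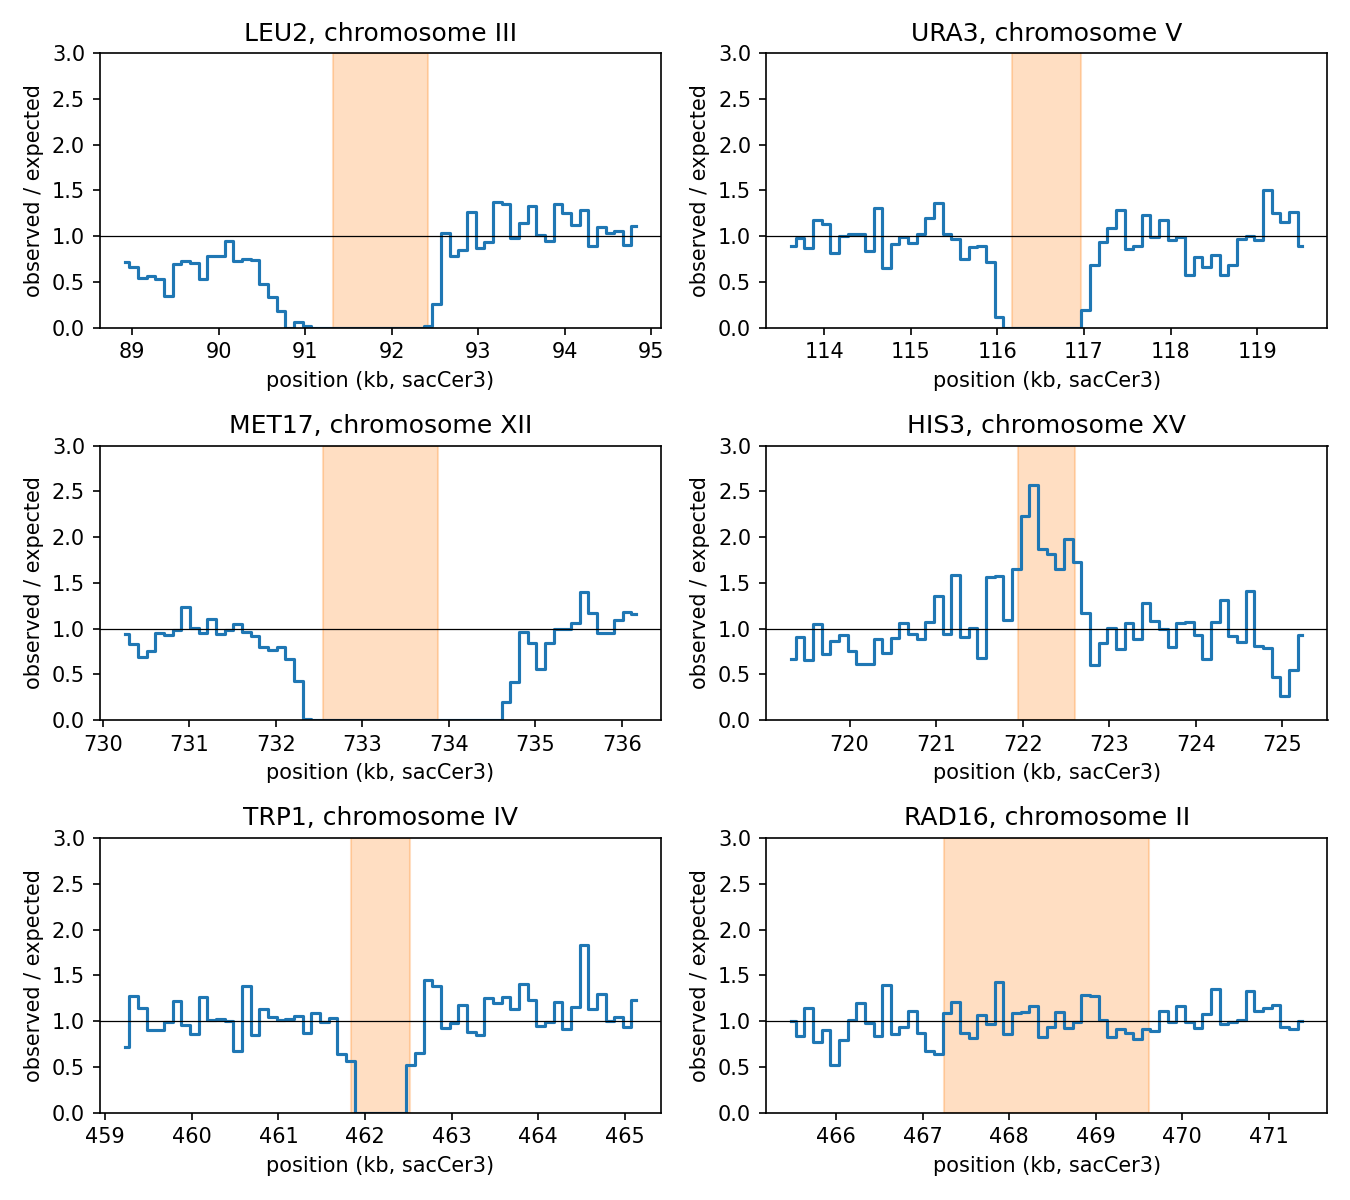
Observed over expected reads in windows of 100 bp around LEU2, URA3, MET17, HIS3, TRP1 and RAD16 in the library labelled wild type, without UV, with positions in kb on the sacCer3 build and the gene shaded. No reads lay in LEU2, URA3 and MET17; TRP1 had a ratio of 0.0692, HIS3 of 2.03 and RAD16 of 1.02 over the whole gene.

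Reads per gene were set against the expected count for 5996 nuclear protein-coding genes with at least 50 expected reads. The median ratio was 1.03, and 90% of genes lay between the 5th percentile of 0.887 and the 95th of 1.18. Counting error alone gave 0.928 to 1.07 in simulated counts. A ratio of at least 1.5 was found for 38 genes and of at most 1/1.5 for 22. The 22 became 13 with each position counted once, 41 at dipyrimidine positions only and, in an alternative chosen after seeing the data, 417 at the median mapping quality. At that quality the expected count was not adjusted for sequence to which reads cannot map uniquely. Of the 38, 2 had under 10% of reads at mapping quality 0 or 1. These were HIS3 and HMRA1, a gene of the silent mating-type cassette, at 1.62 (1.47 to 1.77). Of the 22, 8 had under 10% of such reads, and 8 were genes of Ty transposons. The former 8 include LEU2, URA3 and MET17, which had no reads and so no real share.

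The 8 highest genes by the naming rule lay in or beside tandem repeats. TAR1 (YLR154W-C) and YLR154C-G, inside the ribosomal DNA, had ratios of 54.3 and 54.5. YLR154C-H had 19.1 and RRT15 5.21. YHR052C-B, YHR054C-B, YHR054C and RSC30, at the CUP1 array of chromosome VIII, had 7.42, 7.34, 6.05 and 2.75. Between 77.2% and 100% of the reads in these genes had a mapping quality of 0 or 1, as reads shared between copies have. Below LEU2, URA3, MET17, TRP1 and YLR302C, the lowest genes by the naming rule, which leaves out Ty genes, were SRD1 at 0.498 (0.431 to 0.572), YPL119C-A at 0.526 and SPG3 at 0.533. A stretch without reads from 148663 to 149547 on chromosome III covers part of SRD1 (148238 to 148903), so its ratio is not that of an evenly low gene. Among genes whose reads were mostly unshared, a set chosen after the values were seen, ACB1, an acyl-CoA binding protein, had 1.40, TOA2, a subunit of transcription factor TFIIA, 1.39 and CCW12, a cell wall mannoprotein, 1.37.

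Several groups of genes stood apart from random lists matched on expected count, as a description of this library. Neither the random lists nor the random windows were matched on GC content. Over windows of 1 kb the median ratio rose from 0.911 in the lowest GC decile to 1.05 in the highest. Whether GC content accounts for the list medians was not tested. Of the 13 lists, 5 had medians above and 2 below the central 95% of 10000 random lists. The 18 glycolysis and fermentation genes had a median ratio of 1.09 (random lists 0.990 to 1.07), led by TDH3 at 1.23 and ENO1 at 1.20, with PFK1 at 1.01 and HXK2 at 1.04 lowest. The 10 histone genes had a median of 1.15 (0.946 to 1.10), with HHF2 at 1.30 and HTA1 at 1.24 highest and HTA2 at 0.993 and HTB1 at 1.04 lowest. The 14 heat shock genes had a median of 1.09 (0.977 to 1.07). SSA2 was highest at 1.21, with 28.8% of its reads at mapping quality 0 or 1, followed by SSA4 at 1.13, and HSP78 at 0.969 and HSP82 at 0.988 were lowest. The 96 Ty transposon genes had a median of 1.18 (1.01 to 1.04), from YCL020W at 0.513 and YCL019W at 0.563 to YPR158C-C at 1.73 and YLR157C-A at 1.69, and share reads between copies. The 275 tRNA genes had a median of 1.10 against 0.956 to 1.02 for random windows of the same lengths, with YNCN0015W at 1.82 and YNCP0010W at 1.71 highest and YNCC0008W at 0 of 44.1 expected reads and SUP53 at 0.0583 lowest. YNCC0008W and SUP53 lie at longer stretches without reads on chromosome III, that of SUP53 beside LEU2. The 76 snoRNA genes had a median of 0.920 (0.946 to 1.04), from SNR68 at 0.605 and SNR53 at 0.665 to SNR76 at 1.29 and SNR47 at 1.24. The 4 deleted markers had a median of 0 (0.943 to 1.13). Among the alternatives chosen beforehand, the glycolysis call was lost at positions that are not dipyrimidines (1.06) and the heat shock call at dipyrimidine positions only (1.05), the histone call at positions that are not dipyrimidines (1.09) and at an expected count of at least 200 (1.11), the Ty call without overlapping genes (0.997) and the snoRNA call at dipyrimidine positions only (0.995). With 8 bases of context, an alternative chosen after seeing the data, the glycolysis and heat shock calls were also lost (1.02 and 1.03) and the tRNA median turned to 0.956, below its random range. With reads at the median mapping quality only, also chosen after seeing the data, the glycolysis call was lost although its median rose (1.19). The histone (0.627), tRNA (0.902) and Ty (0) medians turned below their ranges, which were drawn at the same setting. The expected count there was not adjusted for sequence to which reads cannot map uniquely, so lists of repeated genes can fall for this reason alone. Without genes whose reads are shared, also chosen after seeing the data, the Ty call was lost (0.970).

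The other lists lay within the range of random lists in the main setting. The 22 nucleotide excision repair genes had a median of 1.02 (0.984 to 1.06), from TFB5 at 0.774 and TFB1 at 0.899 to RAD23 at 1.11 and RAD33 at 1.10. The 13 DNA damage response genes had 1.03 (0.976 to 1.08), with RNR2 at 1.15 and PHR1, the photolyase gene, at 1.13 highest and DUN1 at 0.887 and HUG1 at 0.949 lowest. The 135 ribosomal protein genes had 1.02 (1.01 to 1.05), from RPS30B at 0.733 and RPL38 at 0.756 to RPL29 at 1.38 and RPS26B at 1.21. The 16 glucose-repressed genes had 1.07 (0.986 to 1.07), with ADY2 at 1.19 and GAL3 at 1.18 highest and FBP1 at 0.931 and GAL10 at 0.958 lowest. This list lay above its random range with each position counted once (1.07) and at dipyrimidine positions only (1.11). The 18 meiosis and sporulation genes had 1.00 (0.987 to 1.07), from ZIP1 at 0.905 and DIT2 at 0.917 to SMK1 at 1.07 and SPS4 at 1.06. The 41 subtelomeric COS, PAU and FLO genes had 1.03 (0.985 to 1.06), from COS4 at 0.852 and PAU9 at 0.857 to PAU8 at 1.35 and PAU2 at 1.30, and share reads between family members. With reads at the median mapping quality only, the ribosomal protein (0.764), meiosis (1.07) and subtelomeric (0.0398) medians lay below their random ranges. Those ranges were drawn at the same setting and are not given here. The meiosis median itself rose from 1.00 in the main setting, so its change of call came from the range.

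**Figure D3:**
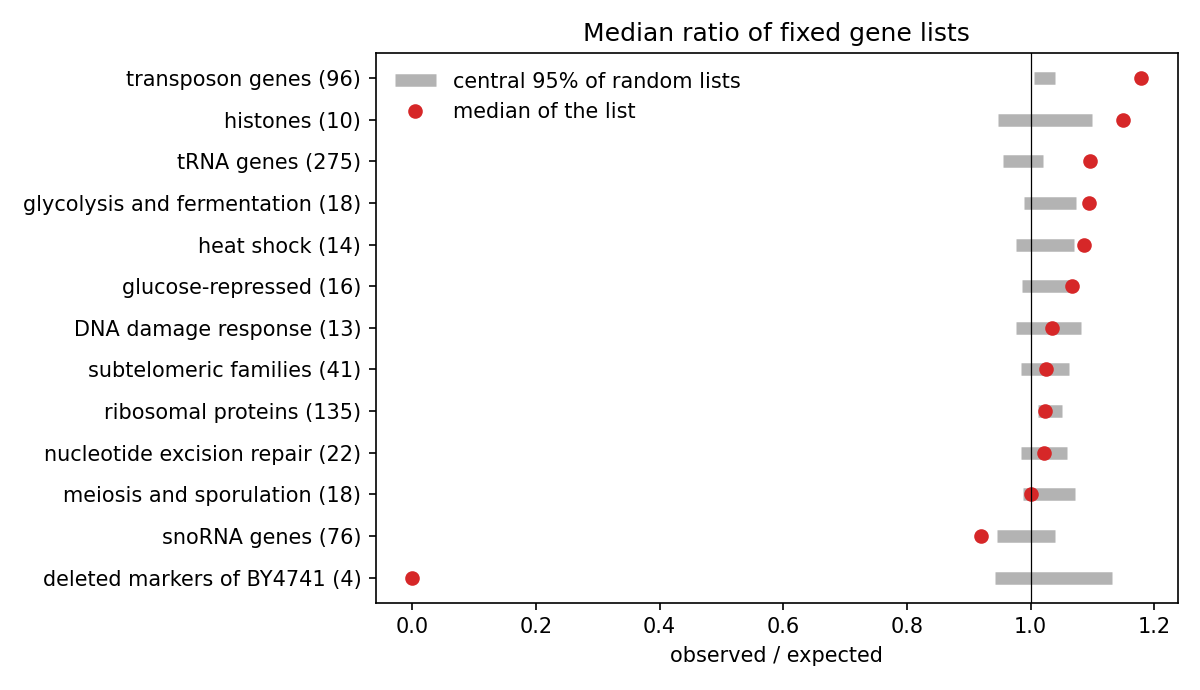
Median observed over expected reads of each fixed gene list (points, number of genes in parentheses) with the central 95% of 10000 random lists (bars) in the library labelled wild type, without UV. Ty transposon genes (1.18), histone genes (1.15), tRNA genes (1.10), glycolysis (1.09) and heat shock genes (1.09) lay above their bars, and snoRNA genes (0.920) and the deleted markers (0) below.

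Repair maps compare the transcribed strand of genes with the other strand, so the background of each strand was measured. Over the 5996 genes the transcribed strand held 47.6% of reads (47.58 to 47.67%), against 49.9% expected from its dinucleotides, a difference of -2.32 percentage points. With 8 bases of context in the expected count the difference was -1.50 points (-1.55 to -1.46), and with reads at the median mapping quality only it was -2.90, both alternatives chosen after seeing the data. With the dinucleotide expectation the difference was below 0 for 4451 genes (74.2%) and on each of the 16 chromosomes, from -2.75 points on chromosome IV to -1.52 on chromosome III. It was -2.39 points for genes on the plus strand and -2.25 for genes on the minus strand. In 271 genes with introns, the coding exons had 47.5% of reads on the transcribed strand (47.3 to 47.8%) and the 281 introns 49.9% (49.4 to 50.4%).

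Among genes with at least 200 reads, the lowest transcribed-strand shares relative to expectation were those of RRT15 (11.4%), TMA23, a ribosome assembly gene (27.8%), PAM16, a mitochondrial import gene (33.2%), and LRP1, an exosome cofactor gene (33.4%). The highest were those of YLR154C-H (94.9%), YLR162W (72.9%), ECM12 (66.4%) and YFL068W (65.0%). RRT15, YLR154C-H and YLR162W lie in or near the ribosomal DNA, and YFL068W at the end of chromosome VI had 100% of its reads at mapping quality 0 or 1. The lists were compared on strand with the dinucleotide expectation, and the random lists were not matched on purine content. Purine content was related to strand share in intergenic windows, as given below. Whether it accounts for the differences between lists was not tested. By list, the median difference was -5.56 points for nucleotide excision repair genes (random lists -4.02 to -0.774). It was -0.808 for ribosomal protein genes (-3.23 to -1.45), 0.757 for glycolysis genes (-4.02 to -0.493), 0.417 for glucose-repressed genes (-3.92 to -0.226) and 0.921 for subtelomeric families (-3.53 to -0.181). The other 5 of 10 lists compared lay within their random ranges. These were DNA damage response, heat shock, histone, meiosis and Ty transposon genes. The deleted markers were not compared, since LEU2, URA3 and MET17 had no reads and so no strand share.

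Coding sequence carried more reads than the DNA on either side of it. The 200 bp upstream of start codons had an observed over expected ratio of 0.912 (0.910 to 0.915), the first 500 bp from the start codon 1.04 (1.03 to 1.04), and the 200 bp downstream of stop codons 0.882 (0.880 to 0.884). Within the first 500 bp the transcribed strand had 0.992 and the other strand 1.08. Upstream, the strands had 0.9003 and 0.924, and downstream 0.886 and 0.878. The contrast was not adjusted for GC content. Over windows of 1 kb the median ratio rose from 0.911 in the lowest GC decile to 1.05 in the highest.

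**Figure D4:**
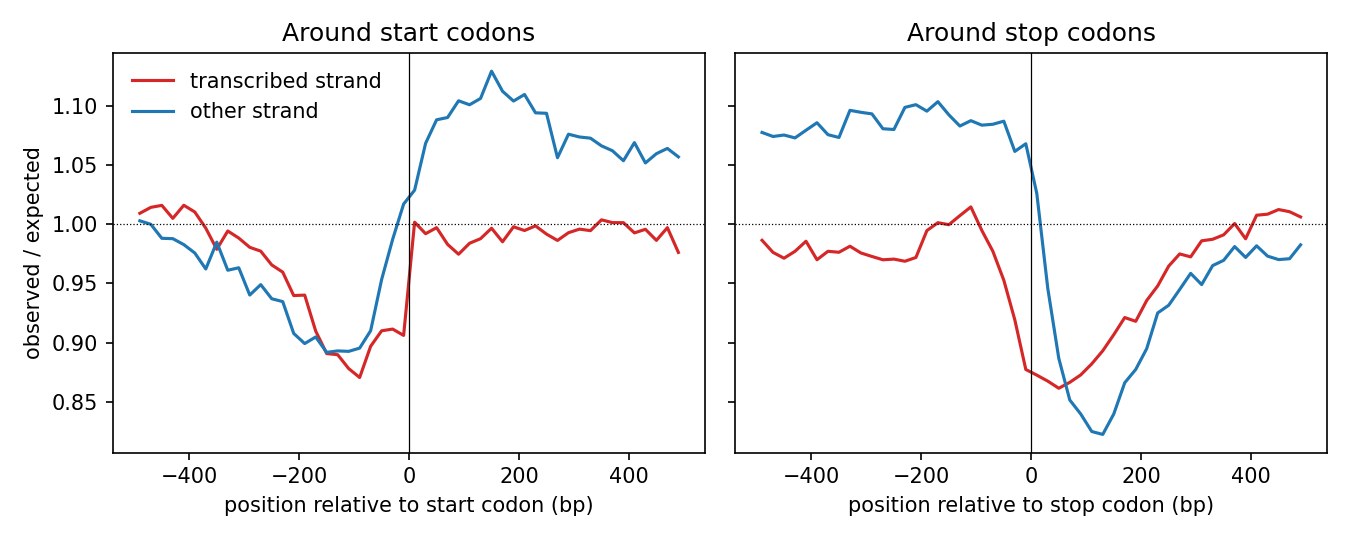
Observed over expected reads in bins of 20 bp around start codons (left) and stop codons (right) of nuclear protein-coding genes, with position in bp on the horizontal axis, for the transcribed strand and the other strand in the library labelled wild type, without UV. Both strands dip outside coding sequence, to 0.912 over the 200 bp upstream of start codons and 0.882 over the 200 bp downstream of stop codons.

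Centromeres, chromosome ends and replication origins had slightly more reads than the rest of the nuclear genome. The ratio to the rest was 1.04 within 20 kb of the 16 centromeres (1.038 to 1.044), 1.03 within 20 kb of chromosome ends (1.025 to 1.032) and 1.02 within 2 kb of the 349 origins outside the ribosomal DNA (1.020 to 1.024). Left of origins the plus strand had 1.02 and the minus strand 1.01, and right of origins 1.02 and 1.04. With reads at the median mapping quality of 42 only, an alternative chosen after seeing the data, the ratio at chromosome ends was 0.447 and that at origins 0.934. The origins near chromosome ends were not left out, and the expected count was not adjusted for sequence to which reads cannot map uniquely.

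The most hit positions lay in the ribosomal DNA, while repeated hits occurred throughout the nuclear genome. Of nuclear reads, 50.3% lay at positions hit more than once, and 46.4% outside the ribosomal DNA, where an even scatter would give 26.0%. The 100 most hit positions held 0.0955% of nuclear reads (0.0933 to 0.0977%), and all 100 lay in the ribosomal DNA. The 5 most hit positions lay on chromosome XII between RDN5-1, a 5S ribosomal RNA gene, and RDN37-2, a ribosomal RNA precursor gene. They started at 460206, 460209, 460677, 460407 and 459831, with 218, 185, 141, 137 and 127 reads. The highest count outside the ribosomal DNA was 40.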

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

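No paired analysis was possible because only 1 library was analysed here. Alternatives were compared with the counting interval of each value, so small shifts count as changes. Causes were not tested unless stated. With each position counted once, the dipyrimidine share was 25.6%, the mitochondrial ratio 1.60, the strand difference -2.01 points, the low genes 13, the upstream ratio to the first 500 bp 0.894 (0.880 in the main setting), ends 1.05, centromeres 1.04 and origins 1.01. At the median mapping quality the dipyrimidine share was 25.7%, the TT ratio 0.962 and the mitochondrial ratio 1.66. Without chromosome XII the plus-strand share was 50.07%. Shifted by 1 base, the dipyrimidine share was 23.1% (5-prime) and 25.5% (3-prime), the TT ratio 0.696 (5-prime), and the CG ratio fell below 1, to 0.986 (3-prime). Expected from length alone, the strand difference was -2.38 points and the upstream ratio 0.883. With dipyrimidine positions only, the strand difference was -2.56 points, the low genes 41, the upstream ratio 0.877, ends 1.03, centromeres 1.05 and origins 1.03, and with the other positions only the strand difference was -2.25 points. Without overlapping genes, where fewer genes were tested, 25 genes were high and 13 low. Without genes within 20 kb of a chromosome end the strand difference was -2.38 points. A threshold of 2 left 14 high and 6 low genes. With a 100 bp window the upstream ratio was 0.893. With 10 kb and 30 kb windows ends had 1.07 and 1.01 and centromeres 1.04 and 1.03. The 100 most hit positions outside the ribosomal DNA held 0.0357% of reads, and the 1000 most hit positions 0.597%.

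Added after seeing the data, 8 bases of context gave a strand difference of -1.50 points, an upstream ratio of 0.924, ends 1.02, centromeres 1.05 and origins 1.03. At the median mapping quality the strand difference was -2.90 points, the low genes 417, the upstream ratio 0.794 and centromeres 1.07, while ends and origins fell below the rest, to 0.447 and 0.934. The expected count at this setting was not adjusted for sequence to which reads cannot map uniquely. Without genes whose reads are shared the strand difference was -2.38 points, with 2 high and 8 low genes. The number of markers below a ratio of 0.1 stayed at 3 of 4 under each alternative run for it. The number of lists outside the random range stayed within 1.5 times that of the main setting, but membership did not stay the same. Of 158 list medians under 13 settings, 19 changed their position relative to random lists, 13 changed side of 1 and 17 moved beyond the interval of the main median without a reversal. Ty transposon genes fell to 0.997 without overlapping genes, to 0.970 without genes whose reads are shared and to 0 at the median mapping quality. The tRNA genes fell to 0.956 with 8 bases of context and to 0.902 at the median mapping quality, and histone genes to 0.627 at the latter. Against matched protein-coding genes the tRNA median was 1.10, above its random range (0.975 to 1.06), and the snoRNA median 0.928, below it (0.980 to 1.06).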

Other observations

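Of the tests in this part, those of the 50-base words of TRP1 and of purine content were set down before their results were seen, and the others were chosen only after the results they bear on were seen, as were the loci of the next paragraphs.

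Mating-type and repeated loci had ratios away from 1, and the reads of most of them had low mapping quality. HMRA1, the a-type gene of the silent cassette, had a ratio of 1.62 (1.47 to 1.77), while HMLALPHA1 had 0.582 and MATALPHA1 0.639, with 96.8% and 96.1% of reads at mapping quality 0 or 1. The copper metallothionein genes CUP1-1 and CUP1-2 had 7.30 and 6.94 per reference copy, with 100% and 99.7% of reads at mapping quality 0 or 1. The sodium pump genes ENA1, ENA2 and ENA5 had 1.97, 1.85 and 1.73, with 78.9%, 99.9% and 89.2% of such reads. The subtelomeric helicase genes YRF1-1, YRF1-5 and YRF1-8 had 1.69, 1.77 and 1.74, each with 100% of such reads.

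Stretches of at least 60 bp without a read occurred at LEU2 (1462 bp), URA3 (1043 bp), MET17 with YLR302C (2339 bp) and TRP1 (606 bp, chromosome IV, 461879 to 462484, 363.1 reads expected). They also occurred at CSS1 (207 bp) and at SUP53 (130 bp), whose stretch ends at 90883, beside the LEU2 stretch that starts at 90980. On chromosome III the stretch at SRD1 (885 bp) ends at 149547 and that at YNCC0008W and YNCC0009C (1742 bp) starts at 149549. These neighbouring stretches are split by few reads and need not be separate events. In the 100 bp left of the TRP1 gap 34 reads lay on the plus strand and 0 on the minus strand, and in the 100 bp right of it 3 and 29. This pattern was not particular to TRP1. The counts were 43 and 1 left and 1 and 23 right of the URA3 gap. At the MET17 gap they were 24 and 0 left and 0 and 22 right. At the LEU2 gap they were 0 and 14 right, but 2 and 3 left, where the SUP53 stretch lies near.

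TRP1 lacked reads over most of its length and HIS3 had a ratio of 2.03 in the library labelled BY4741, a strain that carries a deletion in HIS3 and none in TRP1. Reads shared with another locus are argued against for the gap, since 0.0% of the 557 words of 50 bases in the TRP1 gap occur elsewhere in the reference. A library of the rad16 deletion under the wild-type label is argued against by RAD16 itself, at a ratio of 1.02 (0.966 to 1.07). A candidate explanation for HIS3 is an added copy beside an allele deleted between its HindIII sites, which should bring that stretch to between 0.4 and 0.7 of the rest of the gene. It was at 0.755 (0.637 to 0.890), with ratios of 1.65 inside and 2.18 outside, which leaves this open.

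Coding sequence had fewer reads on the transcribed strand, by 2.32 percentage points, than its dinucleotides gave. Introns, which are transcribed too, differed by -0.0847 points (-0.589 to 0.420), while the exons of the same genes differed by -2.46. This cannot rule out transcription as a cause, since the purine content of introns, which could offset such an effect, was not measured. With 8 bases of context in the expected count the difference was -1.50 points (-1.55 to -1.46), so local sequence does not account for all of it. The coding strand had 3.12 percentage points more purines than an even share. The relation of strand share to purine content in 7044 intergenic windows of 300 bp predicted 83.3% of the difference (80.01 to 86.51%). This interval, from leaving out each chromosome in turn, covers only the spread of that relation over the windows. These windows lay outside gene spans, which run from start to stop codon, so they can hold transcribed flanks. Strand composition over windows of this size may therefore underlie most of the asymmetry, and no biological explanation beyond transcription was tested.

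Read density was higher near centromeres and origins in the main setting, but at the median mapping quality the ratio within 2 kb of origins fell to 0.934. That ratio did not leave out origins near chromosome ends, and its expected count was not adjusted for sequence to which reads cannot map uniquely. Windows of 1 kb also had more reads at higher GC, from a median ratio of 0.911 in the lowest GC decile to 1.05 in the highest. GC content as the whole cause is argued against, since windows within 20 kb of centromeres exceeded windows of the same GC beyond 100 kb by 0.0678 (0.0588 to 0.0768, from leaving out each chromosome in turn). Copy number in replicating cells could give such a pattern, as windows within 5 kb of origins exceeded those over 20 kb away by 0.0353 at the same GC (0.0259 to 0.0446), beyond 100 kb of centromeres and 20 kb of chromosome ends, and by 0.0220 (0.0115 to 0.0325) at the median mapping quality. The comparison near origins repeats the observed excess at matched GC, so it cannot tell copy number from other causes. Chromatin differences near these sites were not tested and stay open.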
